A study of Mus musculus with 17 samples.

How the data were processed

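The series held 17 samples of mouse oocytes and preimplantation embryos, each hybridised to its own Affymetrix MG-U74Av2 array. Per the labels, total RNA was taken through 2 rounds of amplification by in vitro transcription before hybridisation. The deposited values were used: 1 signal intensity per probe set and array for 12488 probe sets, on a linear scale, scaled per array by the authors. The software behind these intensity values, its version and the scaling target were not given in the sources used here, and the table held no detection calls. The mean of the middle 96% of each array's values lay between 150.097 and 150.133, so that no further scaling was applied. The median signal of an array lay between 34.05 and 49.15, 5 values were 0 and 2812 were under 1. The number of arrays, 3 or 4 per stage, limits the precision.

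Signals were taken to log2 after an offset of 11, the 25th percentile of all values. Probe sets were tested when their signal was above 41.1, the median of all values, on at least 3 arrays, and 66 control probe sets were left out. This gave 8067 probe sets. Gene symbols came with the platform's annotation: 10833 probe sets had 1 symbol, 396 had several and 1193 had none. Symbols were brought up to date by Entrez ID through a reference table for 10817 probe sets. For values per gene, the probe set with the highest mean over all arrays among those with exactly 1 symbol stood for its gene, which gave 6044 genes. Gene symbols are used for names alone, and probe sets whose name marks shared or dropped probes can also hybridise with other transcripts.

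Groups were the 5 stages in the sample titles. A linear model with a mean per stage was fitted over all 17 arrays in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), with 12 residual degrees of freedom. The 4 comparisons of consecutive stages and blastocyst minus oocyte were taken from this fit. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and a probe set was called at an adjusted p below 0.05. A moderated F test counted probe sets that differed between any of the stages. No batch was given in the labels, and the replicate numbers in the titles were not used as a block.

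Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 24 lists and 5 comparisons (120 tests), and again with an estimated correlation. Of 48 calls, 5 held with the estimated correlation. The 25 lists covered oocyte and maternal factors, transient 2-cell activation, pluripotency, primitive endoderm, trophectoderm, epithelial junctions and cavitation, ribosomal proteins, proteasome, translation initiation, splicing, RNA polymerase II, nucleolus, oxidative phosphorylation, glycolysis, cholesterol synthesis, DNA replication, mitosis, DNA methylation and chromatin, chaperones, imprinted genes, mRNA storage and decay, and markers of cumulus and granulosa, blood, sperm, and oviduct and uterus cells. Some lists were formed by name pattern, so they also took in a few genes with a like name and another function. The cumulus and granulosa list had 4 measured members and was counted without a test.

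The stages, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule allowed, in each consecutive comparison, the 8 genes with the largest rise and the 8 with the largest fall whose arrays did not overlap between the stages, and up to 4 members of each called list and 2 of each other list in every comparison. It also allowed a set of landmark genes and the 8 genes with the clearest peak at the 2-cell stage. The genes named are a part of those the rule allows, chosen after their values were seen. Of the landmark genes, Zscan4c and Gapdh had no probe set of their own outside the controls and were not analysed here as genes.

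Turnover was the count of probe sets called in consecutive comparisons, set against independent lists of the same sizes and against 100 simulated sets of unchanged groups. The fit was tested on simulated data in which 200 of 8067 probe sets were changed by 0.5, 1 or 2 on the log2 scale, and it called 6, 5, 8, 6 and 12 unchanged probe sets in the 5 comparisons. With so few changed probe sets the adjustment was stricter than in the real data, so the shares called there do not carry over. In simulated list tests, camera called 2 of 2 moved tests and 0 of the others. The simulated genes were drawn independently, so this does not cover lists with correlated members, such as ribosomal proteins (estimated correlation 0.39).

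The alternatives tried were quantile normalization, median centring, other offsets, no filter and a stricter filter on dim signals (above 152.5), no intensity trend, array weights, the replicate number as a block, only the arrays of the stages compared, the mean over a gene's probe sets, an estimated correlation, and each array left out in turn. A scaling of each array on its hybridisation spikes, which are added to the labelled RNA at hybridisation, and a run on plain probe sets alone were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.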

Results

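The data comprised 17 single-colour Affymetrix MG-U74Av2 arrays of mouse preimplantation development, which runs from the oocyte through cleavage of the embryo to the blastocyst, the hollow stage with an inner cell mass and an outer trophectoderm. There were 4 arrays of oocytes, 3 of 1-cell embryos, 3 of 2-cell embryos, 4 of 8-cell embryos and 3 of blastocysts. Per the labels, total RNA was taken through 2 rounds of amplification by in vitro transcription. The labels did not say whether samples of a stage came from separate animals or pools of embryos, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Of the probe sets on the array, 8067 passed the filter on dim signals and stood for 6044 genes. Arrays of the same stage correlated at 0.950 to 0.982 across probe sets, and the highest correlation of any array with an array of another stage ranged from 0.850 to 0.926 (probe sets are not independent replicates). Of the 8067 probe sets, 6834 (84.7%) differed between the stages by limma's moderated F test. Changes below are differences of mean log2(signal + 11) ± SE, a scale that understates the change of dim genes. Where a stage's signal lay below the filter of 41.1, its fold depends on the offset and is not exact. Signals are means ± SD over the arrays of a stage, and adjusted p values are those of limma.

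**Figure D1:**
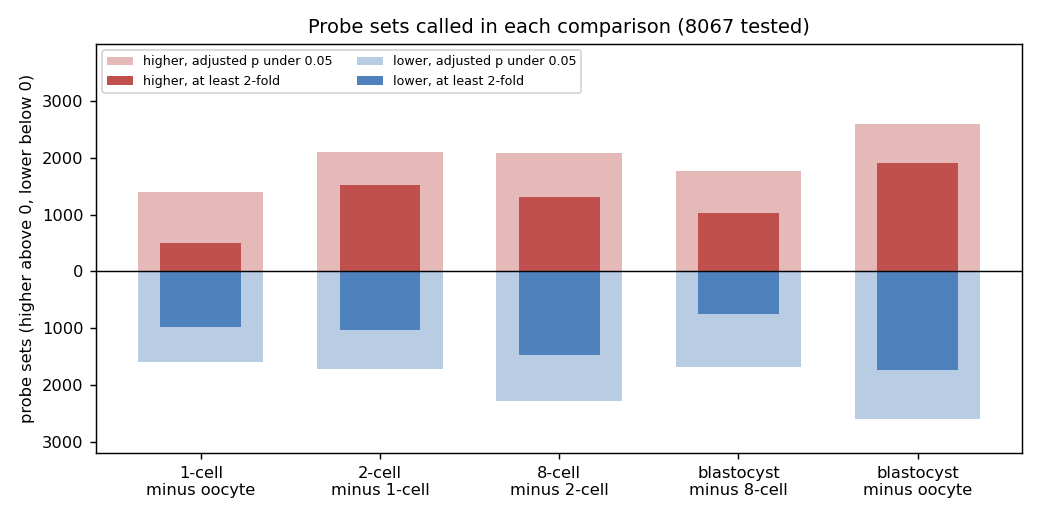
Probe sets called higher (above 0) and lower (below 0) in each of the 5 comparisons, out of 8067 tested. Wide pale bars show all calls and narrow dark bars those with a change of at least 2-fold; blastocyst minus oocyte had the most calls (5184) and 1-cell minus oocyte the fewest (2994).

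The comparison of 1-cell embryos with oocytes spanned fertilisation and lay before the main activation of the embryo's own genome. The labels did not give the maturation stage of the oocytes, so the changes may also include those of meiotic maturation. Many transcripts for ribosomes (20 of 25), oxidative phosphorylation (44 of 65) and the proteasome (24 of 33) were lower in 1-cell embryos, although as lists they were not called with an estimated correlation (adjusted p = 0.134, 0.127 and 0.127). Atp5o, a subunit of the mitochondrial ATP synthase, had a signal of 455 ± 98.5 in oocytes (n = 4) and 12.8 ± 4.03 in 1-cell embryos (n = 3), a 19.4-fold fall (log2 change -4.28 ± 0.23). Cox17, which delivers copper to cytochrome c oxidase, fell by 4.20 ± 0.25 on the log2 scale, and Rpl10a, a protein of the large ribosomal subunit, fell by 4.20 ± 0.23. Among transcripts that rose, Tradd, an adaptor of the tumour necrosis factor receptor, went from 67.3 ± 27.4 to 616 ± 94.8 (log2 change 3.06 ± 0.41), and Mybl1, a Myb family transcription factor, went from 28.0 ± 5.46 to 190.4 ± 60.1 (2.34 ± 0.24).

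The other genes with the largest rises were Gpcpd1, a glycerophosphocholine phosphodiesterase (2.58 ± 0.36), the splicing and transcription cofactor Snw1 (2.21 ± 0.42), the ubiquitin-conjugating enzyme Ube2k (2.12 ± 0.23), the homeobox gene Hoxa7 (2.06 ± 0.21), the Golgi membrane gene Yipf4 (2.02 ± 0.20) and Pex11a, which acts in peroxisome division (2.00 ± 0.20). The largest falls also took in Dppa5a, an RNA-binding protein of pluripotent cells (-4.10 ± 0.18), Smim20 (-3.99 ± 0.26), the translation initiation factor Eif3m (-3.93 ± 0.22) and Ddt, D-dopachrome tautomerase (-3.71 ± 0.26). Of 25 measured ribosomal protein genes, 20 fell, 1 rose and 4 were not called, with the same 20 and 1 adjusted over the list alone. Rpl7 (-3.84 ± 0.19), Rpl41 (-3.68 ± 0.23) and Rps18 (-3.50 ± 0.24) were among those that fell, and limma's camera test placed the list below other genes (adjusted p = 7.51e-12, and adjusted p = 0.134 with an estimated correlation). Of 65 oxidative phosphorylation genes, 44 fell and 3 rose (45 and 4 adjusted over the list alone), with 18 not called (camera adjusted p = 2.41e-13, and adjusted p = 0.127 with an estimated correlation). Uqcrq of complex III (-3.56 ± 0.18) and Ndufb5 of complex I (-2.99 ± 0.18) were examples. Proteasome subunits fell in 24 of 33 cases, rose in 3 and were not called in 6 (24 and 3 adjusted over the list alone), at an adjusted p = 1.21e-08 and an adjusted p = 0.127 with an estimated correlation. Psmd14 changed by -3.64 ± 0.23. Psmb5 was 8.02-fold lower, although another of its probe sets gave -0.07 (adjusted p = 0.896). The 18S ribosomal RNA control probe sets were higher in 1-cell embryos, by 4.41 to 5.74 on the log2 scale, and the hybridisation spikes were higher by 1.14, in the comparison in which these lists fell.

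Chaperones fell in 13 of 22 cases, rose in 1 and were not called in 8 (14 and 1 adjusted over the list alone, camera adjusted p = 2.18e-04, and adjusted p = 0.133 with an estimated correlation). These included Hspa4 (-2.74 ± 0.22) and the chaperonin subunit Cct5 (-2.64 ± 0.18). Nucleolar genes showed 14 falls, 4 rises and 14 members not called of 32 (14 and 4 adjusted over the list alone, adjusted p = 0.00410, and adjusted p = 0.381 with an estimated correlation). The stricter filter ended this list's call (0.0750). Examples were Emg1 (-2.90 ± 0.19) and Nhp2 (-2.60 ± 0.19). The RNA polymerase II list passed narrowly, with 13 members lower, 6 higher and 11 not called of 30 (13 and 7 adjusted over the list alone, adjusted p = 0.0481, and adjusted p = 0.241 with an estimated correlation). Its call ended without oocyte array 2 (adjusted p = 0.0771), without oocyte array 3 (0.0519) and without 1-cell array 3 (0.0869). It also ended with median centring (0.0645), array weights (0.0781), no intensity trend (0.0574), the replicate block (0.0563), the stricter filter (0.114) and plain probe sets alone (0.0562). Polr2l (-2.70 ± 0.16) and Gtf2e2 (-1.99 ± 0.17) were its largest changes. Genes of mRNA storage and decay rose in 11 of 23 cases, fell in 2 and were not called in 10 (12 and 3 adjusted over the list alone, adjusted p = 0.0138, and adjusted p = 0.329 with an estimated correlation), but with the arrays scaled on the hybridisation spikes this list had 0 rises and 9 falls, a median change of -0.52 and no call (adjusted p = 0.0922). The stricter filter ended its call too (0.0599). The deadenylase Cnot7 (1.40 ± 0.20, and -0.28 at another probe set that was not called) and the mRNA-binding protein Ybx1 (1.38 ± 0.17) rose, and Tob1, which recruits deadenylases, fell (-2.04 ± 0.27). With the spike scaling the changes of Cnot7 and Ybx1 were 0.28 and 0.25 and were not called.

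Oocyte and maternal factors went both ways, with 10 higher, 5 lower and 8 not called of 23 (11 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.685). Its median was 0.37 and its mean -0.06, so that these differed in sign, and the median turned with quantile normalization and with the spike scaling. The zona pellucida genes Zp2 and Zp3, which encode the egg coat, changed by -2.42 ± 0.20 and -2.42 ± 0.22. The meiotic kinase Mos changed by -0.88 ± 0.28 (adjusted p = 0.0181), a call that ended without 1-cell array 2 (-0.85, adjusted p = 0.0586). The growth factor gene Gdf9 rose by 0.48 ± 0.15 (adjusted p = 0.0147), but it was not called without 1-cell array 1 (0.40, adjusted p = 0.0822), and with quantile normalization and with the spike scaling its change was -0.35 and -0.65. The maintenance DNA methyltransferase Dnmt1 fell by 0.96 ± 0.17, while the mean over its probe sets gave -0.29 and no call. Beta-actin (Actb) had a change of 0.03 ± 0.17 (adjusted p = 0.918), and -1.05 with the spike scaling. Among markers of other cells, the sperm lactate dehydrogenase Ldhc fell by 2.53 ± 0.32, as the single call of 6 sperm markers (camera adjusted p = 0.801), and the collagen gene Col1a1 rose by 1.04 ± 0.31, as the single call of 13 oviduct and uterus markers (camera adjusted p = 0.639). Col1a1 was not called without 1-cell array 3 (0.90, adjusted p = 0.0547) or with the spike scaling (0.02).

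Over all probe sets, 2994 of 8067 were called between 1-cell embryos and oocytes, 1397 higher and 1597 lower, and 507 and 983 of these changed at least 2-fold. With the spike scaling, chosen after seeing the data, 30 were called higher and 4638 lower, so that rises are stated relative to the arrays' mean signal. In simulated data of this comparison, 2 of 67 probe sets changed by 0.5 on the log2 scale were called, 38 of 67 changed by 1 and 65 of 66 changed by 2. The simulation changed 200 probe sets and called 111, against 2994 in the real data, so its cut on the p-value was stricter. The shares called, here and in the comparisons below, may thus understate those in the real data.

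The comparison of 2-cell with 1-cell embryos covered the main activation of the embryonic genome in the mouse. Many transcripts that were near background in 1-cell embryos were abundant in 2-cell embryos. Crxos, a homeobox gene, went from a signal of 1.77 ± 0.603 (n = 3) to 1969 ± 978 (n = 3), a rise from background that the offset of 11 limits to 144-fold (log2 change 7.17 ± 0.23). Psat1, an enzyme of serine synthesis, rose by 6.89 ± 0.26, and Prps1, which makes the precursor of nucleotide synthesis, by 6.85 ± 0.20. At the same step oocyte transcripts fell, among them H1f8, the oocyte linker histone, from 8667 ± 1944 to 312 ± 56.5 (-4.74 ± 0.23), and Mos, from 2099 ± 97.1 to 139 ± 93.0 (-3.98 ± 0.30).

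Further large rises were those of Guca1a, an activator of guanylate cyclase (6.92 ± 0.21), the autophagy gene Map1lc3b (6.75 ± 0.27), the lysosomal protease gene Ctsl (6.73 ± 0.27), the ubiquitin ligase gene Mkrn1 (6.69 ± 0.22) and Pramel7 (6.54 ± 0.34). Further large falls were those of Rgs2, a regulator of G protein signalling (-4.70 ± 0.26), Sepsecs, which acts in selenocysteine synthesis (-4.30 ± 0.29), the retinoic acid-binding protein gene Crabp2 (-4.18 ± 0.25), Tsc22d1 (-3.82 ± 0.21), Fbxo3 (-3.79 ± 0.26) and the DNA repair nuclease gene Dclre1a (-3.73 ± 0.23). Of 23 oocyte and maternal factors, 18 fell, 0 rose and 5 were not called, and the counts were the same adjusted over the list alone (camera adjusted p = 1.18e-06, and adjusted p = 0.0522 with an estimated correlation). Plasminogen activator (Plat) fell by 3.33 ± 0.27, the germ cell RNA-binding protein Dazl fell by 2.91 ± 0.43 and Gdf9 fell by 2.70 ± 0.16. Transient 2-cell activation genes rose in 9 of 11 cases, with 1 lower and 1 not called and no change of these counts adjusted over the list alone (camera adjusted p = 3.19e-05, and adjusted p = 0.0735 with an estimated correlation). Pramel6 (6.27 ± 0.21), the initiation factor gene Eif1a (4.43 ± 0.20, but 0.64 at another probe set that was not called) and the deubiquitinase gene Usp17la (2.98 ± 0.35) were examples. From the 2-cell to the 8-cell stage this list went both ways, with 5 members higher, 5 lower and 1 not called (camera adjusted p = 0.639). Pramel6 itself was higher still on the 8-cell arrays, at 3424 to 5207. Pluripotency genes rose in 14 of 22 cases, fell in 1 and were not called in 7 (15 and 1 adjusted over the list alone, adjusted p = 7.14e-04, and adjusted p = 0.0522 with an estimated correlation). Dppa4 (5.35 ± 0.24), Fbxo15 (4.15 ± 0.20), Dppa5a (3.42 ± 0.19) and Zfp42 (3.42 ± 0.24) rose. Nanog, a pluripotency transcription factor, rose by 0.63 ± 0.21 at low signals (20.2 ± 4.51 and 38.0 ± 11.9, adjusted p = 0.0159), and this call ended without 1-cell array 1 (adjusted p = 0.0579), 1-cell array 2 (0.0514), 2-cell array 1 (0.0568) or 2-cell array 3 (0.0828). It also ended with quantile normalization (0.148), median centring (0.164), array weights (0.0773), the larger offset (0.0658) and the spike scaling (0.101).

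The ribosomal protein list, lower in 1-cell embryos, was higher in 2-cell embryos, with 20 of 25 members that rose, 1 that fell and 4 not called (21 and 1 adjusted over the list alone, adjusted p = 1.62e-10, and adjusted p = 0.169 with an estimated correlation). The 18S control probe sets changed the other way here too, by -2.42, -3.01 and -4.23. Rpl7 rose by 4.44 ± 0.20 and Rps3 by 4.37 ± 0.23. Nucleolar genes rose in 24 of 32 cases, fell in 1 and were not called in 7 (26 and 1 adjusted over the list alone, adjusted p = 3.66e-08, and adjusted p = 0.127 with an estimated correlation). The largest changes were those of Nop16 (5.16 ± 0.22) and Nhp2 (4.53 ± 0.21). In the RNA polymerase II list 16 members rose, 7 fell and 7 were not called of 30 (17 and 7 adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.184 with an estimated correlation). Its largest changes went both ways, with Taf1d, a factor of RNA polymerase I, at 3.72 ± 0.24 and the general transcription factor Gtf2b at -3.15 ± 0.24. Chaperones rose in 12 of 22 cases, fell in 4 and were not called in 6, also when adjusted over the list alone (adjusted p = 0.0336, and adjusted p = 0.364 with an estimated correlation). Without 2-cell array 3 the list was not called (adjusted p = 0.0608), nor was it with array weights (0.0735), no offset (0.0555), the stricter filter (0.0757) or plain probe sets alone (0.0934). The inducible heat shock genes Hspa1a (2.59 ± 0.41) and Hspa1b (2.24 ± 0.41) and their partner Bag3 (4.06 ± 0.31) rose. DNA replication genes fell in 19 of 37 cases, rose in 6 and were not called in 12 (20 and 7 adjusted over the list alone, adjusted p = 0.00410, and adjusted p = 0.241 with an estimated correlation). The primase subunits parted, with Prim2 at -2.15 ± 0.24 and Prim1 at 2.01 ± 0.23, and the replication genes Rpa1 (-2.43 ± 0.22) and Mcm4 (-1.99 ± 0.17) fell.

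A few markers of other cells were higher in 2-cell embryos, although none of their lists that were tested was called. Ovgp1, the oviduct glycoprotein, had a signal of 44.6 ± 14.2 in 1-cell and 892 ± 329.6 in 2-cell embryos (4.00 ± 0.99, adjusted p = 0.00199), and Ltf, the secreted protein lactotransferrin, had 33.3 ± 34.1 and 209.6 ± 70.6 (2.54 ± 0.91, adjusted p = 0.0266). The Ltf call ended without 1-cell array 1 (adjusted p = 0.0817), 1-cell array 2 (0.102) or 2-cell array 1 (0.0820). Of 13 oviduct and uterus markers, 6 rose, 1 fell and 6 were not called, the same adjusted over the list alone (camera adjusted p = 0.684). The macrophage lysozyme gene Lyz2 rose by 2.57 ± 0.60, as 1 of 2 called among 7 blood cell markers (camera adjusted p = 0.582).

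In all, 3810 of 8067 probe sets were called, 2096 higher and 1714 lower in 2-cell embryos, and 1515 and 1028 of these changed at least 2-fold. With each array centred on its median, the split was 1614 higher and 2435 lower, because the median signal of 2-cell arrays was the highest of the 5 stages (47.3 ± 1.62). In simulated data of this comparison, 4 of 67 probe sets changed by 0.5 on the log2 scale were called, 34 of 67 changed by 1 and 62 of 66 changed by 2.

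**Figure D2:**
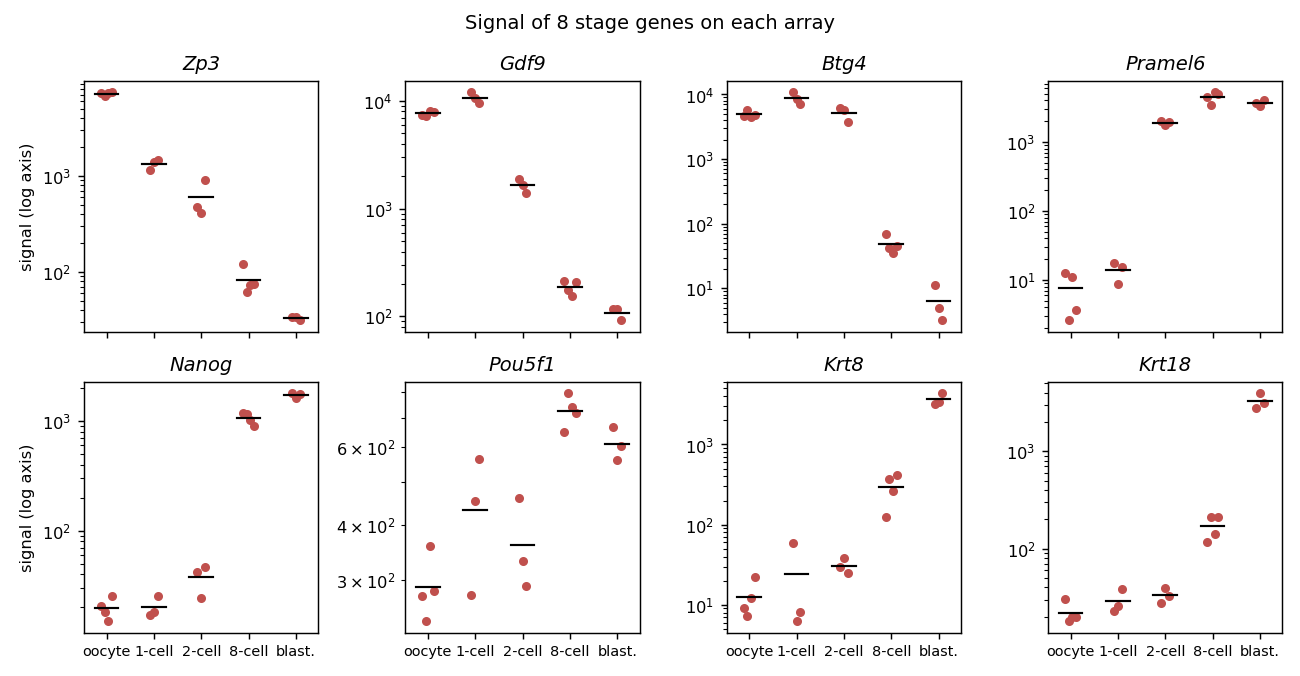
Signal (log axis) of 8 genes on each of the 17 arrays, by stage. Points are arrays and black bars are stage means; the maternal genes Zp3, Gdf9 and Btg4 were lowest in blastocysts, Pramel6 rose from a mean of 13.8 in 1-cell to 1889 in 2-cell embryos and was higher still in 8-cell embryos (3424 to 5207), and Krt8 and Krt18 were highest in blastocysts.

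The comparison of 8-cell with 2-cell embryos covered the later cleavage divisions. Btg4, an adaptor that brings deadenylases to maternal mRNAs, went from 5230 ± 1271 (n = 3) to 48.2 ± 14.6 (n = 4), an 88.5-fold fall (log2 change -6.47 ± 0.21). The oocyte growth factor gene Bmp15 fell by 5.47 ± 0.26 and the oocyte gene Tcl1b1 fell by 6.44 ± 0.16. Bhmt, which passes a methyl group from betaine to homocysteine, rose from 164 ± 124 to 9150 ± 863 (5.96 ± 0.33), and Nanog rose from 38.0 ± 11.9 to 1070 ± 133 (4.49 ± 0.19).

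The other large rises were those of Vnn1, which makes cysteamine (5.82 ± 0.20), the gluconeogenic enzyme Fbp2 (5.72 ± 0.26), Sema4b (4.47 ± 0.20, but 0.29 and 0.35 at its other probe sets, which were not called), the inhibitor of differentiation Id3 (4.24 ± 0.29), Smpdl3a (4.10 ± 0.24) and the nucleolar RNA helicase Ddx21 (4.05 ± 0.18). Other large falls were those of Trim61 (-6.37 ± 0.26), the inositol oxygenase Miox (-6.12 ± 0.19), the cysteine dioxygenase Cdo1 (-5.78 ± 0.25), Mllt3 (-5.56 ± 0.21) and Angel2 (-5.54 ± 0.17). Oocyte and maternal factors fell in 20 of 23 cases, rose in 0 and were not called in 3, also adjusted over the list alone (camera adjusted p = 1.62e-10), and the call held at an adjusted p = 0.0171 with an estimated correlation. Zp3 fell by 2.65 ± 0.22 and Gdf9 fell by 3.07 ± 0.15. Genes of mRNA storage and decay fell in 16 of 23 cases, rose in 3 and were not called in 4, the same adjusted over the list alone (adjusted p = 0.00279, and adjusted p = 0.241 with an estimated correlation). Cnot7 fell by 3.27 ± 0.20 (-0.59 at another probe set) and Lsm14b, a component of stored oocyte mRNA particles, fell by 4.27 ± 0.21.

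Of 33 proteasome subunits, 27 rose, 1 fell and 5 were not called (28 and 1 adjusted over the list alone, adjusted p = 1.62e-10, and adjusted p = 0.112 with an estimated correlation). Psma5 rose by 2.65 ± 0.19 and Psma7 by 2.64 ± 0.20. Of 25 ribosomal protein genes, 22 rose, 0 fell and 3 were not called, the same adjusted over the list alone (adjusted p = 5.65e-10, and adjusted p = 0.184 with an estimated correlation). Rps19 rose by 3.42 ± 0.34 and Rpl8 by 2.73 ± 0.16. Oxidative phosphorylation genes rose in 46 of 65 cases, fell in 6 and were not called in 13, also adjusted over the list alone (adjusted p = 3.00e-08, and adjusted p = 0.241 with an estimated correlation). Ndufa5 (3.50 ± 0.21) and Uqcrb (3.27 ± 0.18) rose, and Cox6b2, a testis form of a cytochrome c oxidase subunit, fell (-2.88 ± 0.24). Chaperones rose in 16 of 22 cases and fell in 2, with 4 not called and no change adjusted over the list alone (adjusted p = 5.09e-05, and adjusted p = 0.124 with an estimated correlation). These included Hspa8 (3.28 ± 0.20) and Cct7 (2.59 ± 0.16). Translation initiation factors showed 23 rises, 3 falls and 12 members not called of 38 (25 and 3 adjusted over the list alone, adjusted p = 5.36e-04, and adjusted p = 0.134 with an estimated correlation). Eif3d rose by 3.13 ± 0.20, and Eif2ak4, a kinase that inhibits initiation and shares the name prefix, fell by 2.71 ± 0.31.

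Pluripotency genes rose in 15 of 22 cases, fell in 4 and were not called in 3 (15 and 5 adjusted over the list alone, adjusted p = 0.00100, and adjusted p = 0.0522 with an estimated correlation). The transcription factor genes Tfcp2l1 (2.83 ± 0.32) and Klf2 (2.59 ± 0.31, with 8-cell array 4 at 45.8 and the others at 118.7 to 136.7) rose, and the cytokine receptor gene Il6st fell (-2.77 ± 0.26). Pou5f1 (Oct4) rose by 1.01 ± 0.20, but its change with the spike scaling was 0.37 and not called. Splicing factors rose in 19 of 35 cases, fell in 4 and were not called in 12 (20 and 4 adjusted over the list alone, adjusted p = 0.0106, and adjusted p = 0.112 with an estimated correlation), but quantile normalization (adjusted p = 0.0522) and plain probe sets alone (0.0616) ended the call and with the spike scaling (0.0704) the list's median was -0.04. Srsf3 rose by 3.46 ± 0.17. Nucleolar genes rose in 16 of 32 cases, fell in 4 and were not called in 12, also adjusted over the list alone (adjusted p = 0.00315, and adjusted p = 0.364 with an estimated correlation). These included nucleolin (Ncl, 1.78 ± 0.15), and with the spike scaling the sign of this list's median turned. Single genes of epithelia and the later trophectoderm rose, among them keratins Krt8 (2.76 ± 0.40) and Krt18 (2.01 ± 0.23) and the claudin Cldn7 (4.04 ± 0.20). Neither the trophectoderm list (8 rose, 2 fell and 11 were not called, adjusted p = 0.124) nor the epithelial list (8 rose, 5 fell and 19 were not called, adjusted p = 0.304) was called, and the medians of both lists turned sign with the spike scaling. Actb rose by 2.15 ± 0.17. The glycolysis genes Ldha (-3.08 ± 0.36) and Pkm (-2.79 ± 0.21) fell, in a list with 8 falls, 4 rises and 3 members not called of 15 (adjusted p = 0.302).

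The 8-cell arrays were not alike for oviduct transcripts, since Ovgp1 was at 6212 on 8-cell array 2 and at 43.1 to 114 on the other 8-cell arrays. Ltf changed by -2.06 ± 0.85 (adjusted p = 0.0465), with 8-cell array 2 at 827.7 and the others at 6 to 11.4. Without that array the change was -3.41 (adjusted p = 2.42e-07), and the call ended when 8-cell array 1 (adjusted p = 0.130), 8-cell array 3 (0.135), 8-cell array 4 (0.150), 2-cell array 1 (0.142), 2-cell array 2 (0.0778) or 2-cell array 3 (0.0729) was left out. Quantile normalization (0.0558), median centring (0.0579), array weights (0.0503), no intensity trend (0.0631), no filter (0.0758), the larger offset (0.0990) and the replicate block (0.0903) ended it too. The smooth muscle myosin gene Myh11 fell by 2.27 ± 0.26. In the comparisons of 8-cell embryos with 2-cell embryos and with blastocysts no list changed its call without 8-cell array 2, while the number of list calls over all 5 comparisons went from 48 to 47. In all, 4364 of 8067 probe sets were called, 2083 higher and 2281 lower in 8-cell embryos, and 1303 and 1475 of these changed at least 2-fold. With the spike scaling 840 were higher and 3239 lower. In simulated data of this comparison, 12 of 67 probe sets changed by 0.5 on the log2 scale were called, 37 of 67 changed by 1 and 64 of 66 changed by 2.

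**Figure D3:**
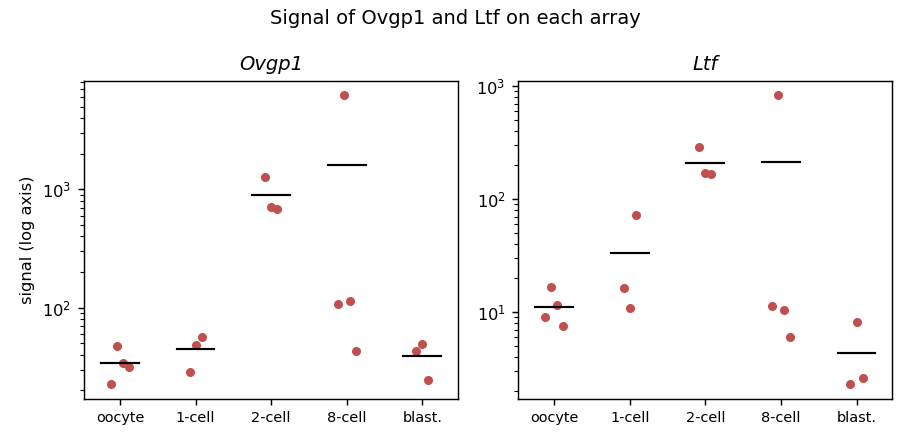
Signal (log axis) of Ovgp1 and Ltf on each array, by stage. Points are arrays and black bars are stage means; both were raised on the 2-cell arrays (means 892 and 210), and among the 8-cell arrays array 2 stood apart for both (6212 and 827.7).

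The comparison of blastocysts with 8-cell embryos covered compaction, cavity formation and the parting of trophectoderm and inner cell mass. Genes of the trophectoderm and of epithelial junctions rose. Id2, an inhibitor of differentiation, went from 116 ± 131 (n = 4) to 4183 ± 1061 (n = 3), a 45.1-fold rise (log2 change 5.50 ± 0.41), and the epithelial keratins Krt18 and Krt8 rose by 4.20 ± 0.23 and 3.69 ± 0.40. The desmosome gene Dsc2 rose by 4.10 ± 0.25, and the glycolytic enzyme Pkm by 3.02 ± 0.21. Klf17, a transcription factor of the early embryo, fell from 482 ± 162 to 4.90 ± 5.29 (-4.95 ± 0.21).

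The other large rises were those of the scaffold protein Pdzk1 (36.8-fold), the alcohol dehydrogenase Adh1 (5.19 ± 0.38), the peptide transporter Slc15a2 (5.11 ± 0.29), the actin-bundling protein Lcp1 (5.03 ± 0.38), the tetraspanin Tspan8 (4.84 ± 0.35), Prxl2a (4.81 ± 0.29, but -0.08 at another probe set that was not called) and the membrane serine protease Tmprss2 (4.57 ± 0.31). The other large falls were those of Bex6 (-5.02 ± 0.18), arginase (Arg1, -4.98 ± 0.25), Tspan4 (-4.76 ± 0.26), Tlcd4 (-4.29 ± 0.24), Dmrtb1 (-4.23 ± 0.24), the stress-induced inhibitor of mTOR signalling Ddit4 (-4.16 ± 0.20) and the transcription factor Foxa1 (-3.89 ± 0.31). Trophectoderm genes rose in 17 of 21 cases, fell in 2 and were not called in 2, also adjusted over the list alone (camera adjusted p = 1.25e-08). Epithelial genes rose in 20 of 32, fell in 2 and were not called in 10, also adjusted over the list alone (adjusted p = 6.98e-06). Both calls held at an adjusted p = 0.0323 with an estimated correlation. Cdx2, the trophectoderm regulator, did not pass the filter (highest signal on any array 15.8). Epcam (3.81 ± 0.31) and the desmosome genes Dsg2 (3.55 ± 0.31) and Dsp (2.92 ± 0.45) rose. E-cadherin (Cdh1) had a change of -0.05 ± 0.21 (adjusted p = 0.859, and 1.05 with the spike scaling). The sodium pump subunit Atp1b1 rose by 0.73 ± 0.25, a call that ended without 8-cell array 1 (adjusted p = 0.0619) or blastocyst array 1 (0.103). Primitive endoderm genes rose in 12 of 19 cases, fell in 1 and were not called in 6 (13 and 1 adjusted over the list alone, adjusted p = 8.45e-04, and adjusted p = 0.127 with an estimated correlation). Examples were the endocytic receptor Lrp2 (2.81 ± 0.26, also in the trophectoderm list), Sparc (2.36 ± 0.34, with 8-cell array 3 at 29 and the others at 2.4 to 4.1) and the basement membrane collagen Col4a1 (2.30 ± 0.36). The stricter filter on dim signals ended this call (adjusted p = 0.0599).

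Oxidative phosphorylation genes rose in 38 of 65 cases, fell in 2 and were not called in 25, the same adjusted over the list alone (adjusted p = 3.04e-06, and adjusted p = 0.329 with an estimated correlation). Examples were the succinate dehydrogenase subunits Sdha (2.13 ± 0.24) and Sdhd (1.67 ± 0.19). Glycolysis genes rose in 10 of 15 cases, fell in 2 and were not called in 3, also adjusted over the list alone (adjusted p = 2.46e-04, and adjusted p = 0.124 with an estimated correlation). These included hexokinase Hk2 (2.65 ± 0.31), the glucose transporter Slc2a3 (2.49 ± 0.32) and Tpi1 (2.34 ± 0.21). Lists that fell here did so relative to the arrays' mean signal. With the spike scaling the medians of the nucleolar, ribosomal protein, RNA polymerase II, maternal and transient 2-cell lists turned sign. Nucleolar genes fell in 22 of 32 cases, rose in 0 and were not called in 10 (25 and 0 adjusted over the list alone, adjusted p = 1.99e-06, and adjusted p = 0.168 with an estimated correlation). Ddx21 (-1.50 ± 0.18) and the RNA polymerase I factors Polr1e (-1.26 ± 0.23) and Rrn3 (-1.27 ± 0.15) fell, with changes of -0.33, -0.18 and -0.11 and no call under the spike scaling. Ribosomal protein genes fell in 15 of 25 cases, rose in 1 and were not called in 9 (17 and 1 adjusted over the list alone, adjusted p = 6.93e-04, and adjusted p = 0.496 with an estimated correlation), but quantile normalization ended the call (adjusted p = 0.344) and the median was 0.60 with the spike scaling. Rps24 fell by 0.96 ± 0.18, with -0.34 and no call under quantile normalization and 0.23 under the spike scaling. RNA polymerase II genes fell in 11 of 30 cases, rose in 4 and were not called in 15, also adjusted over the list alone (adjusted p = 0.0374, and adjusted p = 0.231 with an estimated correlation). The call ended without 8-cell array 3 (adjusted p = 0.0565) or blastocyst array 2 (0.0631), and with median centring (0.0502), the stricter filter (0.0621), plain probe sets alone (0.0609) and the spike scaling (0.399). Taf1a, a factor of RNA polymerase I, fell by 2.34 ± 0.18. Proteasome subunits rose in 12 of 33 cases and fell in 1 (9 and 1 adjusted over the list alone), with no call (adjusted p = 0.118). The list was called without blastocyst array 2 (adjusted p = 0.0327), with quantile normalization (0.0207), with no filter (0.0202) and with the spike scaling (0.0292). Splicing factors were not called as a list (1 rose, 9 fell and 25 were not called, adjusted p = 0.227), with a median whose sign turned with the spike scaling. Their member Srsf1 changed by -1.20 ± 0.22 at its brightest probe set but by 1.22 and 0.73 at its other probe sets, each called, and its change with the spike scaling was -0.17 and not called.

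Maternal factors fell in 12 of 23 cases, rose in 2 and were not called in 9, also adjusted over the list alone (adjusted p = 6.39e-04, and adjusted p = 0.127 with an estimated correlation). These included Omt2b (-3.68 ± 0.19). Transient 2-cell genes fell in 8 of 11 cases with 0 higher and 3 not called, the same adjusted over the list alone (adjusted p = 0.00520, and adjusted p = 0.184 with an estimated correlation). The cell cycle inhibitor Cdkn1a (-1.73 ± 0.23) and Hspa1b (-1.45 ± 0.38) fell, and neither was called with the spike scaling (-0.60 and -0.34). Pluripotency genes went both ways, with 10 higher, 7 lower and 5 not called of 22 (10 and 8 adjusted over the list alone, camera adjusted p = 0.853). Sox2 rose by 3.66 ± 0.24 and Nanog by 0.69 ± 0.19, and Fbxo15 fell by 2.03 ± 0.18. Pou5f1 had a change of -0.25 ± 0.20 (adjusted p = 0.354, and 0.93 with the spike scaling, which was called). Actb rose by 1.09 ± 0.17 at its brighter probe set and fell by 1.48 at the other. The mean signals of the beta-actin control probe sets, left out of the test, were higher in blastocysts. They went from 4854 to 10002 (3'), from 2159 to 6669 (middle) and from 1244 to 4543 (5'). The actin control's log2 ratio of 3' to 5' signal was 0.82 lower on blastocyst than on 8-cell arrays (log2 change -0.82), a measure of RNA and labelling that differed between the same stages as these lists, and the spikes changed by -1.19. Of 13 oviduct and uterus markers, 3 fell and 10 were not called (1 fell adjusted over the list alone, camera adjusted p = 0.190), while with the spike scaling 3 rose and the list was called (adjusted p = 0.00723) at a median of 0.11, below the 0.90 of all probe sets. These included Cd24a (-1.83 ± 0.30, not called with the spike scaling at -0.75) and Ovgp1 (-2.45 ± 0.93, adjusted p = 0.0383), whose change was -0.93 without 8-cell array 2 (adjusted p = 0.0302) and was not called without blastocyst array 1 (adjusted p = 0.0721), 2 (0.0641) or 3 (0.121). It was not called either with no filter (0.0626), no intensity trend (0.0565), the larger offset (0.0508) or the spike scaling (0.0522). Without 8-cell array 2, trophectoderm genes still gave 17 rises and 2 falls (adjusted p = 5.40e-09) and epithelial genes 20 and 2 (adjusted p = 8.11e-06).

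In all, 3432 of 8067 probe sets were called, 1760 higher and 1672 lower in blastocysts, and 1031 and 744 of these changed at least 2-fold. Under the spike scaling 4641 were higher and 193 lower. In simulated data of this comparison, 8 of 67 probe sets changed by 0.5 on the log2 scale were called, 38 of 67 changed by 1 and 64 of 66 changed by 2.

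**Figure D4:**
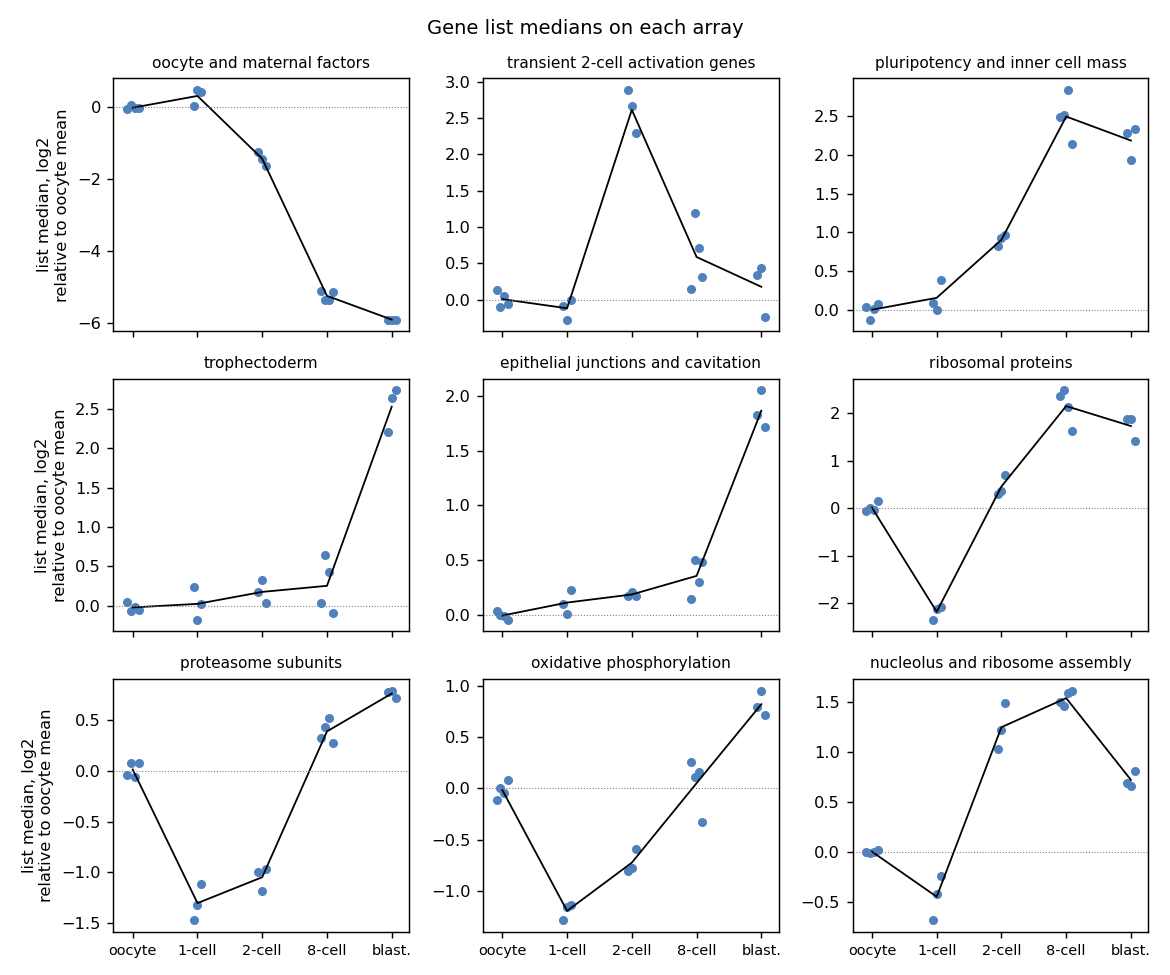
Median over the members of 9 fixed gene lists on each array, as log2 signal relative to the oocyte mean, by stage. Points are arrays and lines join stage means; ribosomal protein genes dipped in 1-cell embryos (median change -2.08) and trophectoderm genes rose in blastocysts (2.60), while the falls of the ribosomal protein, nucleolar, maternal and transient 2-cell medians from 8-cell embryo to blastocyst and the nucleolar rise from 2-cell to 8-cell embryo turned sign with the spike scaling.

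The comparison of blastocysts with oocytes gave the net change over the course. All 23 of the 23 measured oocyte and maternal factors fell, also adjusted over the list alone (camera adjusted p = 5.25e-14), and the call held at an adjusted p = 0.0115 with an estimated correlation. Btg4 went from 4966 ± 608 (n = 4) to 6.43 ± 4.21 (n = 3), a fall to background that the offset of 11 limits to 289-fold (log2 change -8.18 ± 0.21), and the oocyte genes Omt2b and Bcl2l10 changed by -7.93 ± 0.19 and -7.77 ± 0.23. Another Bcl2l10 probe set gave 0.10 and was not called. Krt8 rose from 12.7 ± 6.68 to 3655 ± 592 (7.30 ± 0.40) and Nanog from 19.7 ± 4.44 to 1726 ± 87.1 (5.83 ± 0.19). Pluripotency genes rose in 19 of 22 cases, fell in 1 and were not called in 2, also adjusted over the list alone (adjusted p = 1.20e-06), and this call held at an adjusted p = 0.0148 with an estimated correlation.

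Zp3 fell by 7.35 ± 0.22, Gdf9 fell by 6.01 ± 0.15 and Dnmt1 fell by 3.43 ± 0.17, while another Dnmt1 probe set was not called (0.30). Among pluripotency genes Tfcp2l1 (6.08 ± 0.32, and 2.42 at another probe set, which was the brighter one without blastocyst array 3 and then gave 2.39), Klf5 (5.57 ± 0.32) and Zfp42 (4.71 ± 0.23) rose. Trophectoderm genes rose in 17 of 21 cases, fell in 2 and were not called in 2, the same adjusted over the list alone (adjusted p = 1.02e-05, and adjusted p = 0.0735 with an estimated correlation). Examples were the fatty acid-binding protein Fabp3 (7.13 ± 0.37), Krt18 (6.64 ± 0.23) and Id2 (6.26 ± 0.41). Epithelial genes rose in 23 of 32 cases, fell in 4 and were not called in 5, also adjusted over the list alone (adjusted p = 1.15e-04, and adjusted p = 0.0522 with an estimated correlation). Examples were Epcam (5.83 ± 0.31), the junctional adhesion molecule F11r (5.26 ± 0.22) and Cldn7 (5.48 ± 0.20). Primitive endoderm genes rose in 14 of 19 cases, fell in 2 and were not called in 3, the same adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.241 with an estimated correlation), among them Lrp2 (3.93 ± 0.26) and the receptor gene Pdgfra (2.87 ± 0.35, but 0.06 at another probe set that was not called), and the stricter filter (adjusted p = 0.282) and plain probe sets alone (0.0702) ended the list's call. Glycolysis genes rose in 10 of 15 cases, fell in 2 and were not called in 3, also adjusted over the list alone (adjusted p = 0.0274, and adjusted p = 0.314 with an estimated correlation), with Hk2 at 5.51 ± 0.31 and Slc2a3 at 4.23 ± 0.32 (oocyte array 3 at 4.4 and the others at 20.9 to 25.1).

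Ribosomal protein genes rose in 20 of 25 cases, fell in 1 and were not called in 4, also adjusted over the list alone (adjusted p = 2.36e-06, and adjusted p = 0.314 with an estimated correlation). Rps19 rose by 3.23 ± 0.34 and Rps3 by 3.22 ± 0.22. Nucleolar genes rose in 19 of 32 cases, fell in 5 and were not called in 8 (20 and 6 adjusted over the list alone, adjusted p = 0.00315, and adjusted p = 0.364 with an estimated correlation). The largest change was that of Nop16 (4.88 ± 0.21). Oxidative phosphorylation genes rose in 40 of 65 cases, fell in 9 and were not called in 16, the same adjusted over the list alone (adjusted p = 7.14e-04, and adjusted p = 0.499 with an estimated correlation). Cytochrome c (Cycs) rose by 3.44 ± 0.19, and Cox6a2, a muscle form of a cytochrome c oxidase subunit, fell by 3.73 ± 0.29. Proteasome subunits rose in 20 of 33 cases, fell in 5 and were not called in 8, also adjusted over the list alone (adjusted p = 0.00941, and adjusted p = 0.499 with an estimated correlation), with Psmd13 at 3.61 ± 0.28. The proteasome list was not called with the spike scaling (adjusted p = 0.0922) or with plain probe sets alone (0.0592). Chaperones rose in 12 of 22 cases, fell in 3 and were not called in 7 (13 and 3 adjusted over the list alone, adjusted p = 0.0109, and adjusted p = 0.300 with an estimated correlation). Cct6a rose by 4.51 ± 0.32. Genes of mRNA storage and decay fell in 14 of 23 cases, rose in 5 and were not called in 4 (15 and 5 adjusted over the list alone, adjusted p = 0.0243, and adjusted p = 0.364 with an estimated correlation). Cnot7 fell by 3.87 ± 0.20 and the poly(A)-binding protein gene Pabpc1 rose by 3.80 ± 0.21. The stricter filter (adjusted p = 0.179) and plain probe sets alone (0.0616) ended the list's call. Mitosis genes fell in 18 of 30 cases, rose in 5 and were not called in 7, also adjusted over the list alone (adjusted p = 0.0423, and adjusted p = 0.346 with an estimated correlation). The checkpoint kinase Ttk (-3.24 ± 0.19) and the centriole kinase Plk4 (-2.14 ± 0.21) fell and the spindle motor Kif11 rose (2.27 ± 0.28). The list's call ended without oocyte array 2 (adjusted p = 0.0567), blastocyst array 1 (0.0580) or blastocyst array 2 (0.0867), and with median centring (0.0638), no intensity trend (0.0574), the stricter filter (0.0757), plain probe sets alone (0.0702) and the spike scaling (0.104).

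Transient 2-cell genes went both ways, with 5 higher, 5 lower and 1 not called of 11, also adjusted over the list alone (adjusted p = 0.808). Pramel6 rose by 7.68 ± 0.20. Where a gene has several probe sets, as 1032 did, these went both ways for 50 genes in this comparison. Eif1ax fell by 1.67 ± 0.20 at its brighter probe set and rose by 1.63 at the other, so its direction was not settled. Actb rose by 3.99 ± 0.17. Among oviduct and uterus markers Muc1, a mucin that epithelia also express, rose by 1.55 ± 0.46 and Myh11 fell by 3.83 ± 0.26 (oocyte array 2 at 139.8 and the others at 190.3 to 200.8), 11 of 13 were not called and the list was not called (adjusted p = 0.754). The actin control's 3' to 5' ratio changed by -0.97 on the log2 scale between these stages. In all, 5184 of 8067 probe sets were called, 2597 higher and 2587 lower, and 1913 and 1726 of these changed at least 2-fold. With the spike scaling 1861 were higher and 2996 lower. In simulated data of this comparison, 3 of 67 probe sets changed by 0.5 on the log2 scale were called, 33 of 67 changed by 1 and 63 of 66 changed by 2.

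Consecutive comparisons were also set against each other to find transient patterns. Transcripts with a peak at the 2-cell stage, higher than in 1-cell embryos and then lower in 8-cell embryos, included Sowaha (5.67 ± 0.30 and then -5.13 ± 0.28), Tcstv3 (2.90 ± 0.27 and then -4.54 ± 0.25), the sialic acid synthase Nans (3.55 ± 0.25 and -3.11 ± 0.23), lactate dehydrogenase A (Ldha, 4.18 ± 0.39 and -3.08 ± 0.36) and the kinase gene Hipk1 (4.19 ± 0.28 and -2.95 ± 0.26). Others of the 8 genes with the clearest peak were the mitochondrial trafficking gene Trak2 (3.52 ± 0.27 and -2.82 ± 0.26), Zfp639 (2.94 ± 0.32 and -2.92 ± 0.30, with 8-cell array 2 at 32.7 and the others at 102.9 to 121.1) and Ifng, interferon gamma (3.31 ± 0.30 and -2.96 ± 0.28, with 8-cell array 3 at 18.5 and the others at 2.5 to 3.4). Tcstv1, a 2-cell gene, fell by 4.93 ± 0.28 from 2-cell to 8-cell embryos. In all, 527 of 8067 probe sets rose and then fell around the 2-cell stage, 388 fell and then rose, 820 rose in both comparisons and 724 fell in both. Independent lists of the same sizes would give 593, 443, 541 and 485. Simulated unchanged groups gave 0.01 or fewer on average, but without any change hardly a probe set can be called, so this says nothing of turnover. Around the 1-cell stage 816 probe sets fell and then rose and 760 rose and then fell, against 415 and 297 for independent lists, while 115 rose and 205 fell in both comparisons, against 363 and 339. Around the 8-cell stage the counts were 660 that rose and then fell, 617 that fell and then rose, 466 that rose and 385 that fell in both, against 432, 498, 454 and 473.

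Because consecutive comparisons share the arrays of a stage, the correlation of their changes across probe sets lies below 0 with no effect at all. It was -0.413 around the 1-cell stage (-0.533 in simulated unchanged groups), with a covariance of -0.450 against a simulated -0.0443. Around the 2-cell stage it was 0.162 (-0.534 simulated), with a covariance of 0.271 against -0.0444, and around the 8-cell stage -0.117 (-0.428 simulated), with a covariance of -0.148 against -0.0333. When the 8-cell arrays were divided into 2 parts of 2 arrays each in the 6 possible ways, so that the comparisons shared no array, the mean counts around the 8-cell stage were 486.5, 489.2, 372.8 and 323.8 and the mean covariance was -0.105. With fewer arrays per comparison these counts cannot be set against the independent lists above, and none were computed for the divided groups. The 1-cell and 2-cell groups had 3 arrays each and could not be divided into parts of 2 arrays, so part of the excess of opposite changes around the 1-cell stage may come from the shared arrays. Under the spike scaling the 2-cell peak count was 684, while 82 fell and then rose, 331 rose in both and 462 fell in both around that stage, and with median centring 629 fell and then rose. The spike scaling also moved other stages: the patterns around the 1-cell stage were 1388 that fell and then rose, 10 that rose and then fell and 1 that rose in both (193 with array weights), and around the 8-cell stage 1940, 63 and 57 that fell in both.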

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

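The tests chosen only after the result was seen were those of stage-regulated transcription on the 8-cell arrays, of whole oviduct or uterus tissue, and the 3 tests of the Gapdh signal.

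For 7 of 176 groups of 4 arrays tested, 1 array lay far from the others, where chance gives about 8.8. On the 8-cell arrays, Ifng was 18.5 on array 3 (2.5 to 3.4 on the others), Sparc 29 on array 3 (2.4 to 4.1), Klf2 45.8 on array 4 (118.7 to 136.7), Zfp639 32.7 on array 2 (102.9 to 121.1) and Ltf 827.7 on array 2 (6 to 11.4). On the oocyte arrays, Myh11 was 139.8 on array 2 (190.3 to 200.8 on the others) and Slc2a3 4.4 on array 3 (20.9 to 25.1). Control probe sets, which the comparisons did not use, also differed between stages. For each control named here the largest change over its probe sets and the 5 comparisons is given, so its other probe sets changed less. The 18S ribosomal RNA control was 5.74 higher on the log2 scale in 1-cell embryos than in oocytes (middle probe set, adjusted p = 2.14e-13). The beta-actin control was 4.38 higher in blastocysts than in oocytes (5' probe set, adjusted p = 3.05e-13). The Gapdh control was 3.91 higher in blastocysts than in 8-cell embryos (3' probe set, adjusted p = 1.96e-11). The transferrin receptor control was 4.58 higher in 2-cell than in 1-cell embryos (3' probe set, adjusted p = 2.12e-12).

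The fall of ribosomal protein, oxidative phosphorylation and proteasome transcripts in 1-cell embryos, with median changes of -2.08, -1.13 and -1.31 but no list call with an estimated correlation (adjusted p = 0.134, 0.127 and 0.127), was set against a pair of technical explanations. Under quantile normalization and median centring the highest of the 3 medians was -0.996. Both moved the median change of all probe sets little, from 0.04 to 0.09, so they could hardly have removed falls of this size. The falls thus do not hang on the choice among these scalings, but the test says nothing of the spike scaling, which was not part of it. Each median lay at percentile 0 of 10000 random lists matched on mean level, which argues against a bias with brightness, although random lists do not carry the correlation between the members. A shorter poly(A) tail, which the labelling may miss, and a change of the transcripts at fertilisation, or before it if the oocytes were immature, which the labels do not say, stay open as hypotheses that were not tested here. The higher 18S signal in the same comparison was not explained by a test.

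The signal of Ovgp1 and Ltf on 8-cell array 2 and on the 2-cell arrays was the next pattern. For Ovgp1 the gap of 8-cell array 2 to the next 8-cell array was 5.64 on the log2 scale. Such a gap within a stage argues against regulation with stage as the source in that sample, although the gap is part of the pattern and no separate evidence. For the 2-cell arrays regulation with stage stays open and was not tested. If RNA of oviduct cells were in both, the 37 other genes that stood apart on 8-cell array 2 could be higher in 2-cell embryos too, but their median change of 0.15 lay at percentile 60.25 of matched random lists, while those apart on 8-cell arrays 1, 3 and 4 (49, 25 and 14 genes, against 39 on array 2 with Ovgp1 and Ltf) lay at 3.26, 95.69 and 77.74, which decides nothing. Of the 11 other measured members of the oviduct and uterus list, 2 were highest on 8-cell array 2. By the rule as first written, so few would have spoken against whole tissue. After the result was seen, the rule was made more cautious for dim members. The median signal of the 11 on the 8-cell arrays was 47.55, and 2 had an 8-cell mean above 152.5. Members this dim cannot exclude whole tissue, so the question stays open. RNA of oviduct cells in that sample therefore remains a candidate source, from Ovgp1 at 6212 and Ltf at 827.7.

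The low Gapdh control signal in 8-cell embryos (a mean of 191 at the 3' probe set, after 1141 in 2-cell embryos and before 2980 in blastocysts) was the last pattern. The spikes were 0.65 higher on 8-cell than on 2-cell arrays, which argues against array scaling as the cause, and the actin 3' to 5' log2 ratio differed by -0.066, which argues against shorter RNA. The Gapdh control's own log2 ratio was 1.14 in 8-cell and 2.71 in 2-cell embryos, with changes of -2.50, -1.73 and -0.90 at the 3', middle and 5' probe sets, so the fall depended on the probe set, for a reason that was not tested. The glycolysis list was not called lower in 8-cell embryos (adjusted p = 0.302), so a fall of glycolysis transcripts as a group may or may not be part of it. Regulation of Gapdh itself with stage was not tested.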

How the results depend on the processing

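The spike scaling and the run on plain probe sets were the tests chosen only after the result was seen.

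Each count of called probe sets stayed within 1.5 times its value in all alternatives run, except 4668 for 1-cell minus oocyte with the spike scaling, as did the 2-cell peak count. The ranges with 1 array left out were 2492 to 2813, 3386 to 3680, 3907 to 4269, 2877 to 3398 and 4858 to 5020 for the comparisons in the order given, 6702 to 6874 for any stage, 46 to 48 for list calls and 426 to 531 for the 2-cell peak. Over the other alternatives chosen before the data were examined they were 2556 to 3661, 3001 to 4501, 3296 to 4604, 2612 to 3573, 3678 to 5580, 4558 to 7734 and, for the peak, 353 to 678. List calls were 40 to 50, except 5 with an estimated correlation, and plain probe sets gave 2488, 3151, 3614, 2806, 4268, 5558 for any stage and 40 list calls. With the replicate number as a block, which shares only a number, the counts were 2847, 3800, 4241, 3302 and 5096.

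The spike scaling moved the median change of all probe sets to -0.89, 0.23, -0.59, 0.90 and -0.39, and for 2-cell minus 1-cell median centring and quantile normalization gave -0.22 and -0.13. It split the calls into 30 higher and 4638 lower, 1911 and 887, 840 and 3239, 4641 and 193, and 1861 and 2996. Changes that turned with it were Gdf9 (-0.65) and Actb (-1.05) in 1-cell minus oocyte and Rps24 (0.23), Pou5f1 (0.93) and Cdh1 (1.05) in blastocyst minus 8-cell. Gdf9 was also -0.35 with quantile normalization. In blastocyst minus 8-cell, the mean over probe sets gave -0.20 for Actb and 0.25 for Srsf1, and the stricter filter 1.22 for Srsf1, because another probe set then stood for the gene. The turns with the spike scaling follow from its shift of whole arrays. The spikes changed by 1.14 from oocytes to 1-cell embryos and by -1.19 from 8-cell embryos to blastocysts. The means over probe sets join values that went both ways, 1.09 and -1.48 for Actb and -1.20, 1.22 and 0.73 for Srsf1. For Gdf9 with quantile normalization the cause was not tested. Of 4606 other gene values 4545 stayed called or not called as before, 52 lost the call and 9 turned. A turn was counted only where a call was made, so values not called in either setting could change sign. Of 2481 list values, most from lists with no call, 2387 stayed called or not called as before (some with a median that turned sign with the spike scaling), 86 lost the call and 8 gained it, and of 252 turnover counts 241 stayed within 1.5 times.

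The dim end of the signal limits what was tested, since probe sets near background did not pass the filter.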

Other observations

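The tests in this part were all chosen before the data were examined.

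Genes of DNA methylation and chromatin changed without a common direction. Of 33 measured members, 10 rose and 9 fell from the 1-cell to the 2-cell stage (10 and 9 adjusted over the list alone, camera adjusted p = 0.758). The histone deacetylase gene Hdac1 rose by 4.35 ± 0.27 and the histone acetyltransferase gene Kat2b by 3.60 ± 0.28, and Kat2b was still 4.57 ± 0.26 above the oocyte in blastocysts. The maintenance methyltransferase gene Dnmt1 fell by 1.74 ± 0.18 at this step and by 1.08 ± 0.17 from the 2-cell to the 8-cell stage, where the mean over its probe sets was not called (-0.40). Uhrf1, which brings Dnmt1 to replicating DNA, fell by 3.29 ± 0.36 from the 2-cell to the 8-cell stage and rose by 2.71 ± 0.36 in blastocysts. The Polycomb gene Cbx2 fell by 3.55 ± 0.25 from the 2-cell to the 8-cell stage, while another of its probe sets was not called (-0.43). Mitosis genes were not called from the 1-cell to the 2-cell stage, with 7 that rose and 12 that fell of 30 (7 and 13 adjusted over the list alone, adjusted p = 0.272), but Cdk1, the kinase that drives entry into mitosis, rose by 2.86 ± 0.21 and its activating phosphatase Cdc25c by 3.67 ± 0.19.

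Imprinted genes were not called as a list in any comparison, and from the 8-cell embryo to the blastocyst 5 rose and 2 fell of 13, the same adjusted over the list alone (adjusted p = 0.538). The amino acid transporter gene Slc38a4 rose by 2.79 ± 0.24, to 4.23 ± 0.24 above the oocyte, and the growth factor gene Igf2 by 2.47 ± 0.35. Mest fell by 3.30 ± 0.29 from the 2-cell to the 8-cell stage and lay -3.53 ± 0.29 from the oocyte in blastocysts. Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 1.73 ± 0.26 from the 1-cell to the 2-cell stage. The cholesterol synthesis list was not called either, with 7 rises and 6 falls of 15 at the 2-cell stage, the same adjusted over the list alone (adjusted p = 0.941). From the oocyte to the blastocyst, 0 of 7 blood cell markers rose and 0 fell by limma at the adjusted threshold (adjusted p = 0.835), 4 of 6 sperm markers fell (adjusted p = 0.236), and 1 of 4 cumulus and granulosa cell markers fell.

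Other splits of the arrays were counted for each count of calls. For 1-cell minus oocyte, 1 of 35 splits, the real one, gave as many called probe sets (2994, highest of the others 1375). For 8-cell minus 2-cell it was 1 of 35 (4364, highest of the others 2834), for blastocyst minus 8-cell 1 of 35 (3432 and 1965) and for blastocyst minus oocyte 1 of 35 (5184 and 3581). This argues against an arbitrary grouping of these arrays, although 1 of 35 is the smallest share that 35 splits can give. The splits do not reach chance differences beyond these samples, whose origin from separate animals or pools the labels did not give. For 2-cell minus 1-cell, 10 splits are too few for a share under 0.05 (3810, highest of the others 2), and the count was 1 of 10. For any stage 1 of 100 splits, the real one, gave as many (6834, highest of the others 3019), which argues against an arbitrary grouping among these samples only. For the 2-cell peak it was 1 of 100 (527, highest of the others 0), but each of the other splits drawn gave 0, so this says nothing of a peak beyond chance overlap, for which independent lists would give 593. For list calls 4 of 100 splits, the real one included, gave as many as the real 48, a share under the 0.05 set beforehand. The highest of the others was 53, above the real value. Random splits that mix stages can thus also call many lists, and the number of list calls by itself does not set the stages apart.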
